A study of Mus musculus with 6 samples.

How the data were processed

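Total RNA from mouse aorta was purified on silica columns, per the labels' protocols, and 6 libraries were sequenced, 3 wild-type and 3 EC-Jag1KO. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the assigned fragments of the library) for 35275 genes, with 1 column per sample and with gene coordinates, length, biotype and description per the file headers. STAR, HTSeq and edgeR are named in the submitters' processing notes with no role or version, and the build named there is mm10; the annotation release, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, overlapping genes may share reads, and near-identical genes (alpha- and beta-globins, antibody chains) are uncertain. Coordinates are those of the table; of 34490 genes with an identifier in GENCODE M21, 24919 have the same chromosome, start and end there.

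In the deposited FPKM values, value times gene length sums to the same total in every library, and each value is a whole multiple of what 1 read is worth: 211650 of 211650 values (100%) came out within 0.05 of a whole number of reads. The recovered depth is 19889910 to 25914325 reads in genes per library. At the median gene length, 3 reads correspond to 0.0378 to 0.0492 FPKM, so counting limits the values of genes near that level, among them Aqp5, Mmd2 and Lcn2 in some libraries. Depth was used to judge precision and for 2 added alternatives on recovered reads; since the unit is FPKM, no count model was the main test. No per-sample column was left unused.

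Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries (12165) were tested with limma 3.58.1 in R 4.3.3, with genotype as the only term, an intensity trend in the variance moderation, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Jag1 was also tested with an exact two-sided permutation test. Of 33 gene lists, 31 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31. A gene's p adjusted over a list alone covers the tested genes of that list and was not corrected for the number of lists. The lists covered the Notch pathway, canonical Notch targets, smooth muscle, endothelial, matrix and signalling genes, other cell types of the tissue, stress, and metabolism; 775 of 782 listed symbols were matched to the table, 5 of them through an older symbol. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

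Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Jag1; up to 10 genes per direction that pass the adjusted threshold with groups that do not overlap and a mean of at least 5 FPKM in the higher group, filled up by smallest unadjusted p and named as not passing; and in each list up to 4 passing members or otherwise the 2 of smallest p. Predicted genes, unnamed clones, pseudogenes, Xist and Y-linked genes were left out of the second part. A list member that the rule names is not reported here. Alternatives covered the pseudocount, the filter, scaling, the variance model, sample weights, thresholds, the replicate number as a block, tissue levels as covariates, biotype, other list tests, and each library left out. Added after the data were seen were sex as a covariate, removal of a loess trend with gene length (span 0.5), voom on recovered reads with and without quality weights, 2 further sets of libraries left out, the calls adjusted over a list alone with each library left out, and an estimated correlation without the filter for the lymphocyte and mesothelial lists.

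The gene test was checked on 5 simulated data sets of 12161 to 12185 genes with the spread of these libraries. It recovered 19.7% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 77.9% of those changed 4-fold, with 7 false calls per set. The simulated genes vary independently, which real genes do not. Over the 5 sets 335, 335 and 330 genes were changed by these folds, which eases the adjusted threshold. These rates therefore do not carry over to the real libraries, where 0 genes passed. The list test recovered a shifted list in 5 of 5 sets and called 1 other list. That list, contractile smooth muscle, was shifted by more than its observed mean of -0.10, again in independent genes. The check therefore does not cover shifts as small as those observed or lists whose genes vary together. Chi-square statistics per degree of freedom between libraries were 30.8 to 94.5, so no pair is 1 library entered more than once.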

Results

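RNA from whole mouse aorta was sequenced in 6 libraries, 3 from wild-type animals and 3 from EC-Jag1KO animals, which lack the Notch ligand Jagged1 in endothelial cells. The series addresses what the loss of Jagged1 in mature endothelium does to the vessel wall, including the state of its smooth muscle. The aorta holds endothelium, smooth muscle and adventitia together, so each value is a level in the whole tissue. Reads assigned to genes numbered 23630029, 25130933 and 25705412 in the wild-type libraries and 21897973, 19889910 and 25914325 in the EC-Jag1KO libraries. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples.

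Jag1, the targeted gene (ENSMUSG00000027276, minus strand of chromosome 2, 137081456 to 137116644 in mm10), stood at 12.4 ± 3.8 FPKM in wild-type and 14.2 ± 5.1 FPKM in EC-Jag1KO aorta (SD, n = 3 each). The wild-type libraries had 9.86, 10.6 and 16.9 FPKM, and the EC-Jag1KO libraries had 13.5, 9.42 and 19.6 FPKM, on 1052 to 2852 reads per library. The log2 fold change was 0.16, with a 95% interval from -0.50 to 0.81, and the exact two-sided permutation test of the 6 values gave p = 0.7, where 3 against 3 cannot go below 0.1. The log2 fold change was -0.091 without EC-Jag1KO replicate 3, 0.38 without wild-type replicate 3 and 0.40 without EC-Jag1KO replicate 2, and it was 0.021 and 0.071 without wild-type replicates 1 and 2. Smooth muscle and other cells of the wall also make Jag1, and a value over the whole gene counts reads outside a deleted exon, so this level does not check the deletion in the endothelium.

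Among Notch pathway genes, Notch3, the receptor characteristic of vascular smooth muscle, was the member that stood apart. It measured 16.1 ± 1.5 FPKM in wild-type and 9.90 ± 0.83 FPKM in EC-Jag1KO aorta (n = 3 each), a log2 fold change of -0.64, with all 3 EC-Jag1KO libraries below all 3 wild-type libraries. Notch3 passed the limma test adjusted over the list alone, at an adjusted p of 0.015 over the 31 tested pathway genes and 0.0047 over the 10 tested canonical Notch targets, but not over all genes, where its adjusted p was 0.259. Over the targets it passed with each library left out in turn (highest adjusted p 0.0307), and over the pathway list it did not pass without wild-type replicate 1 (0.0833), wild-type replicate 3 (0.0524), EC-Jag1KO replicate 1 (0.0950) or EC-Jag1KO replicate 2 (0.0639). Nrarp, a Notch target that feeds back on the pathway, lay the other way, at 4.78 ± 1.28 against 8.01 ± 2.06 FPKM. The effector Heyl, chosen after its values were seen, stood at 49.9 ± 8.2 against 36.1 ± 5.8 FPKM, and the effectors Hes1 and Hey2, chosen in the same way, differed by log2 fold changes of -0.32 and -0.26, with intervals that span 0. The list means were -0.035 for the pathway and -0.11 for the targets, with adjusted p of 0.459 and 0.162 in camera. Camera called the targets lower with both female libraries left out (adjusted p = 0.0325), a setting chosen after the data were seen, and the adjusted p with an estimated correlation in all 6 libraries was 0.853. The mean of the targets was -0.055 without EC-Jag1KO replicate 2 (adjusted p = 0.446) and -0.15 without EC-Jag1KO replicate 3 (0.0710).

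**Figure D1:**
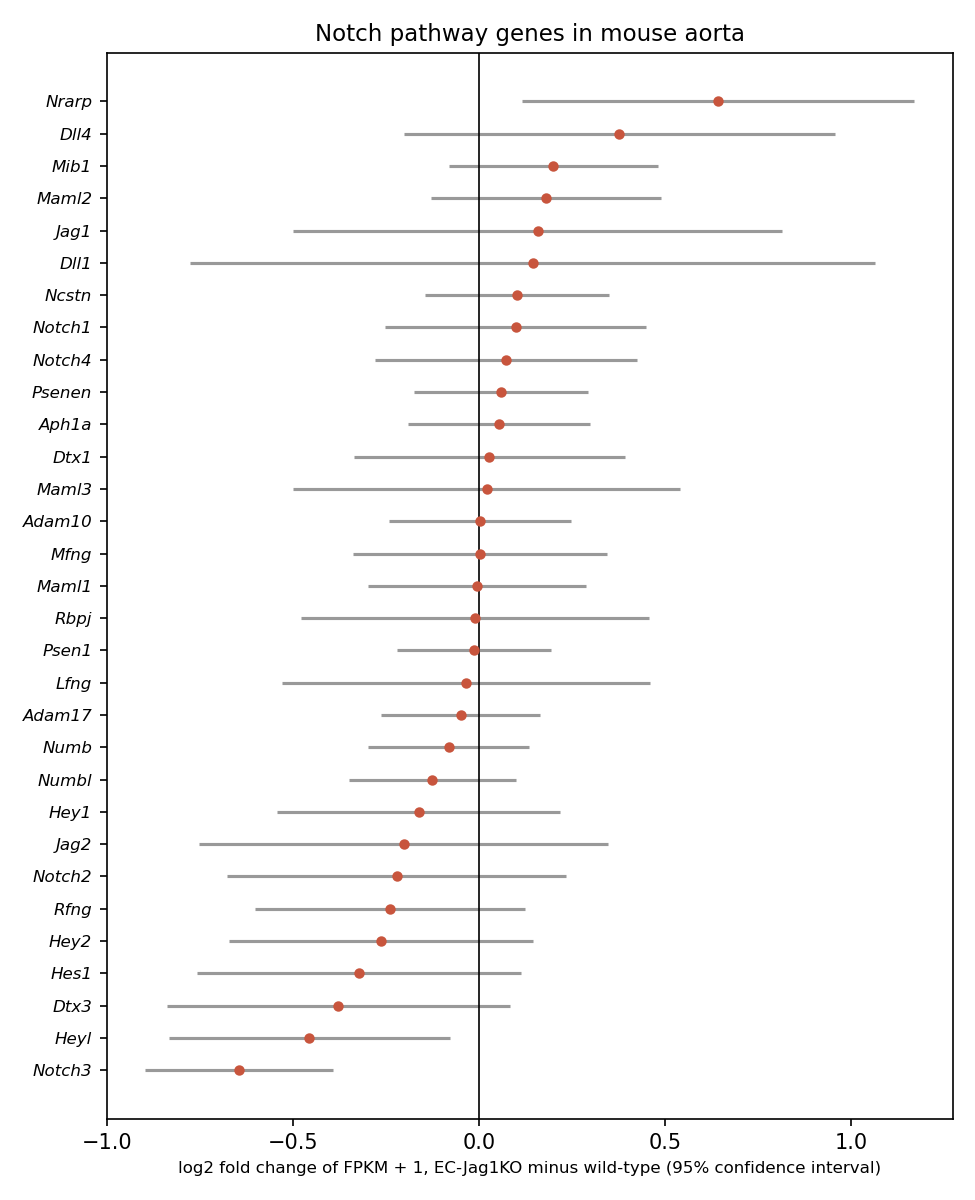
Log2 fold change of FPKM + 1 in EC-Jag1KO against wild-type aorta on the horizontal axis for the 31 tested Notch pathway genes, with 95% confidence intervals as bars. Notch3 lies lowest at -0.64 and Nrarp highest at 0.64, while Jag1 lies at 0.16 with an interval from -0.50 to 0.81.

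Across all genes, no difference passed the adjusted threshold, and the genes of smallest p that met the conditions of the naming rule are given as values. Bcam, which encodes a laminin receptor, measured 578 ± 16 FPKM in wild-type and 351 ± 4.3 FPKM in EC-Jag1KO libraries (n = 3 each), a log2 fold change of -0.72. F3, the tissue factor that starts coagulation, stood at 93.5 ± 6.0 against 58.9 ± 2.9 FPKM. Smoc1, a matricellular protein gene, stood at 121 ± 22 against 241 ± 23 FPKM, and Adm, which encodes the vasodilator adrenomedullin, at 13.4 ± 3.4 against 27.8 ± 2.3 FPKM. Of 12165 genes with a mean of at least 1 FPKM, 0 passed limma's moderated test at an adjusted p of 0.05, and the smallest adjusted p was 0.232. At an unadjusted p under 0.05 there were 938 genes, 517 higher and 421 lower in EC-Jag1KO, where 608 would be expected by chance. Splits of the libraries that mixed the genotypes gave 201 to 1073 such genes, so an excess over 608 also arises without grouping by genotype. Recovered reads tested with limma voom also gave 0 genes, and voom with library quality weights gave 43, both chosen after the data were seen. Array weights gave 1647, with a weight of 14.7 on EC-Jag1KO replicate 1 and 0.259 to 1.61 on the other libraries. Leaving out EC-Jag1KO replicate 1 gave 4 genes past the adjusted threshold, the pseudogenes Gm14287, Eif3s6-ps2, Rpl3-ps1 and Gm12191, named after their values were seen. In all 4 the left-out library lay near the wild-type libraries, so these calls arose because it was removed. Gm12191 stood at 176 FPKM in it and at 88.7 to 170 FPKM in wild-type, against 3.90 and 2.55 FPKM in EC-Jag1KO replicates 2 and 3. The count at an unadjusted p under 0.05 was 601 without wild-type replicate 2, 594 without EC-Jag1KO replicate 1 and 1437 without EC-Jag1KO replicate 2.

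Among genes that met the conditions of the naming rule, the 10 of smallest p on the higher side had log2 fold changes of 0.62 to 2.61. None of these 10 passed the adjusted threshold. Lctl had the largest, from 1.70 ± 1.42 FPKM in wild-type to 14.2 ± 4.1 FPKM in EC-Jag1KO libraries (n = 3 each); it overlaps Zwilch, and reads may be shared between them. Gdf15, a stress-induced cytokine of the TGF-beta family, was at 1.11 ± 0.12 against 5.68 ± 1.60 FPKM, a log2 fold change of 1.63 with an SE of 0.19. Sytl5 stood at 1.07 ± 0.24 against 7.87 ± 3.79 FPKM, and Gria1, a glutamate receptor subunit gene, at 1.59 ± 0.66 against 6.18 ± 1.39 FPKM. Heph, which encodes the copper-dependent iron oxidase hephaestin, stood at 1.48 ± 0.04 against 5.26 ± 1.34 FPKM. Il17ra, the receptor chain for interleukin 17, had 3.03 ± 0.38 against 6.22 ± 0.29 FPKM. Socs2, a suppressor of growth hormone signalling, had a log2 fold change of 0.62, and C1galt1, an enzyme of mucin-type glycosylation, 0.90. Among genes outside the naming rule, picked after their values were seen, Mmd2 had 0.316 ± 0.339 against 4.38 ± 0.86 FPKM, and the water channel gene Aqp5 had 0.0257 ± 0.0444 against 2.46 ± 0.89 FPKM, on 0, 3 and 0 reads in wild-type libraries.

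On the lower side, the 10 genes of smallest p under the same conditions, again none past the adjusted threshold, had log2 fold changes of -0.43 to -1.27. Mmp3, the matrix protease stromelysin, had the largest at -1.27, with 47.2 ± 14.9 FPKM in wild-type and 18.6 ± 2.8 FPKM in EC-Jag1KO libraries (n = 3 each). Fbln1, which encodes the matrix protein fibulin-1, stood at 69.9 ± 6.2 against 38.2 ± 5.2 FPKM. Enpep, the aminopeptidase that cleaves angiotensin II, had 7.77 ± 0.40 against 4.31 ± 0.57 FPKM. Pdgfrl and Pnldc1 had log2 fold changes of -0.66 and -0.67, Fam132a -0.50, and Abr, a regulator of small GTPases, -0.43. The naming rule required groups that do not overlap, so all of these 20 genes have that property by selection. Among all tested genes 1651 had it (13.6%, where chance gives 10% for 3 against 3). Of the 43 genes that voom with library quality weights called, 15 were among these 20. Both sets were ranked on the same libraries, so this overlap is not independent evidence.

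**Figure D2:**
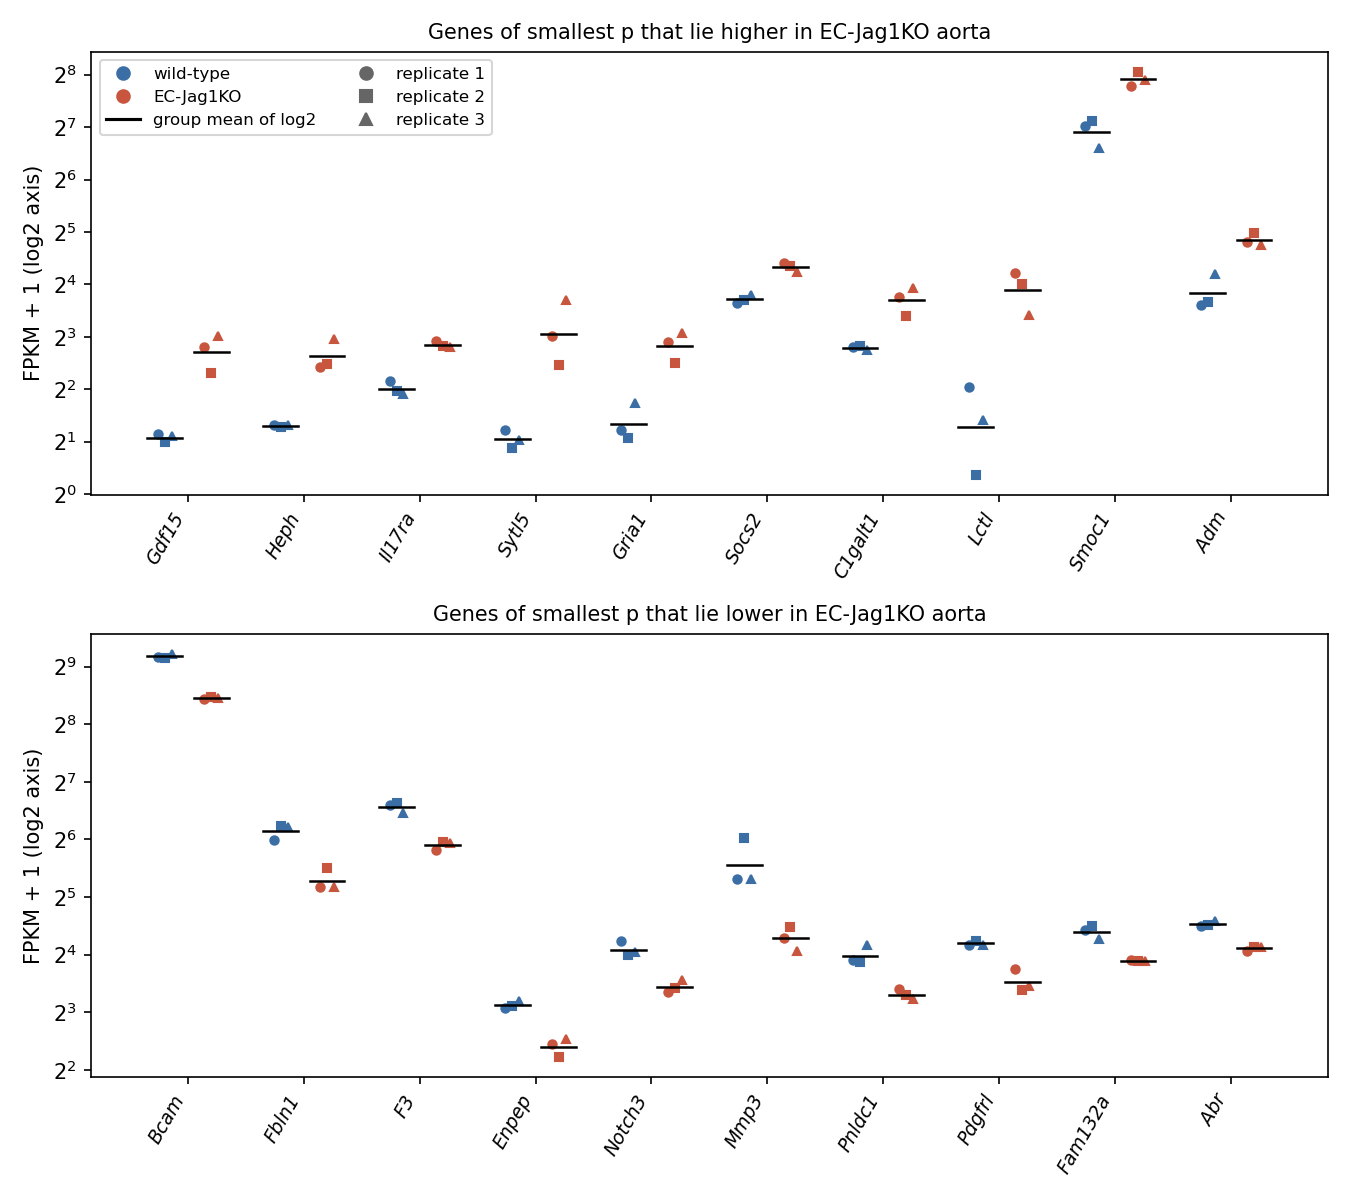
FPKM + 1 on a log2 axis for the genes of smallest p that met the naming rule, 10 on the higher side (upper panel) and 10 on the lower side (lower panel). Points are libraries, marker shapes give the replicate number and lines give group means of log2 values. Bcam lies at 578 FPKM on average in wild-type and 351 FPKM in EC-Jag1KO libraries with no overlap.

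Genes of the elastic fibre moved in opposite directions. Fbln1 fell, from 69.9 ± 6.2 to 38.2 ± 5.2 FPKM, when tested over the list alone, with an adjusted p of 0.0041 in limma. Over all genes its adjusted p was 0.240, and the adjustment over a list alone does not correct for the number of lists. Fbln5, whose product is needed for elastic fibre assembly, rose over the list alone, from 114 ± 14 to 199 ± 24 FPKM, a log2 fold change of 0.80 with an adjusted p of 0.0049. Fbln2, named after its values were seen, rose as well, from 47.5 ± 6.1 to 74.8 ± 8.4 FPKM (list-alone adjusted p = 0.0092). Fbln1 and Fbln5 passed over the list with each library left out in turn, and Fbln2 did not without wild-type replicate 1 (0.0501). Eln, the elastin gene, also named after its values were seen, stood at 769 ± 133 against 609 ± 183 FPKM, within the replicate spread. Of 19 tested members, 3 passed adjusted over the list alone and 0 over all genes, and the list's mean log2 fold change was 0.046, with a camera adjusted p of 0.795. In limma's fry, which asks whether the list's genes change in either direction without comparing them with other genes, the adjusted p over the 31 lists was 0.0028, and 0.0406 or less with each library left out.

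Matrix proteases and their inhibitors split in the same way. Mmp3 fell over the list alone (adjusted p = 0.010 in limma), while Ctsk, the elastin- and collagen-cleaving cathepsin K, rose from 24.98 ± 2.5 to 34.9 ± 2.4 FPKM (list-alone adjusted p = 0.030). Adamts2, the procollagen N-propeptidase, named after its values were seen, rose from 43.8 ± 4.2 to 60.7 ± 5.5 FPKM over the list alone (adjusted p = 0.030). Of 20 tested members, 3 passed over the list alone and 0 over all genes. Mmp3 passed over the list with each library left out, while Ctsk and Adamts2 passed in 2 of 6 such fits. Both failed without wild-type replicate 1 (0.0968 and 0.0968), wild-type replicate 3 (0.0548 and 0.112) or EC-Jag1KO replicate 1 (0.0848 and 0.0848). Ctsk also failed without EC-Jag1KO replicate 2 (0.0545) and Adamts2 without EC-Jag1KO replicate 3 (0.0670). The list mean was -0.00035, while its median of 0.049 and the camera test pointed up, with an adjusted p of 0.919. The fry test of change in either direction gave an adjusted p of 0.0035, which was 0.0718 without wild-type replicate 2, 0.0728 without wild-type replicate 3 and 0.0917 without EC-Jag1KO replicate 1. Among 29 fibrillar collagen and matrix genes, Fmod, the fibromodulin gene, stood at 72.1 ± 17.2 against 39.6 ± 4.5 FPKM and Tnc, the tenascin-C gene, at 24.8 ± 3.1 against 17.0 ± 4.8 FPKM. In this list 0 members passed over the list alone, and the mean was 0.0068 (camera adjusted p = 0.841), or -0.14 with a camera call (0.0213) when both female libraries were left out. With an estimated correlation the adjusted p of this list in the full set was 0.976. Among 27 basement membrane and receptor genes, Lama5 stood at 47.3 ± 3.7 against 35.9 ± 2.9 FPKM and Itga3 at 67.2 ± 2.7 against 54.3 ± 3.4 FPKM, with 0 passing and a mean of -0.022 (camera adjusted p = 0.302), or -0.045 with a camera call (0.0370) without both female libraries. The adjusted p with an estimated correlation in the full set was 0.853.

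Contractile smooth muscle genes were slightly lower in EC-Jag1KO aorta as a list. Smtn, the smoothelin gene of contractile smooth muscle, stood at 390 ± 22 FPKM in wild-type and 282 ± 19 FPKM in EC-Jag1KO libraries (n = 3 each), and Cald1, the caldesmon gene, at 460 ± 28 against 347 ± 34 FPKM. Myocd, the smooth muscle coactivator myocardin, named after its values were seen, lay the other way at 29.0 ± 2.3 against 41.2 ± 10.9 FPKM. Of 31 members, 22 lay lower and 9 higher, 0 passed over all genes or adjusted over the list alone, and the mean log2 fold change was -0.10. Camera with its preset correlation called the list (adjusted p = 0.0090), and with an estimated correlation the adjusted p was 0.853. The call ended without wild-type replicate 2 (adjusted p = 0.163), EC-Jag1KO replicate 1 (0.0518) or EC-Jag1KO replicate 3 (0.125, mean -0.053), under quantile normalization (0.0714, mean -0.093), with the adipocyte covariate (0.152, mean -0.084) and without both wild-type replicate 2 and EC-Jag1KO replicate 3 (0.385, mean -0.030).

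Genes of modulated smooth muscle, the state in which contractile genes are lost, went both ways. Comp, the cartilage oligomeric matrix protein gene, stood at 38.5 ± 17.5 against 14.4 ± 2.3 FPKM, while Lgals3, the galectin-3 gene, had a log2 fold change of 0.57. None of the 23 members passed, and the mean was -0.040 (camera adjusted p = 0.343). Without both female libraries camera called this list lower (mean -0.11, adjusted p = 0.0370). In the full set the adjusted p with an estimated correlation was 0.853. Of 38 genes of excitation and calcium handling 0 passed. Rock2, a protein kinase gene, stood at 43.0 ± 7.9 against 55.8 ± 0.7 FPKM, with a list mean of -0.013 (camera adjusted p = 0.515), or -0.059 with a camera call (0.0370) without both female libraries. For excitation genes the adjusted p with an estimated correlation was 0.976 in the full set. Unfolded protein response genes were lower as a list, with the chaperone genes Pdia6 at 68.0 ± 4.2 against 53.7 ± 2.7 FPKM and Calr at 256 ± 21 against 203 ± 17 FPKM. Of 24 members, 17 lay lower and 0 passed singly, the mean was -0.10, and camera gave an adjusted p of 0.027, which was 0.853 with an estimated correlation. That call ended without wild-type replicate 2 (0.324), EC-Jag1KO replicate 1 (0.1205) or EC-Jag1KO replicate 3 (0.132, mean -0.032), under quantile normalization (0.0714, mean -0.099), with the adipocyte covariate (0.269, mean -0.087), without both female libraries (0.0509, mean -0.048) and without both wild-type replicate 2 and EC-Jag1KO replicate 3 (0.548, mean -0.0072). Without EC-Jag1KO replicate 2 its mean was -0.17. EC-Jag1KO replicate 3, which stands apart from the other libraries, had the lowest contractile list level, 7.81 against 7.91 to 8.05 in the other 5.

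Endothelial genes were not called as a list. Eng, the endoglin gene, stood at 28.2 ± 2.3 FPKM in wild-type and 39.0 ± 2.6 FPKM in EC-Jag1KO aorta (n = 3 each), though Fpgs and Ak1 overlap it and reads may be shared between them. Cd34 stood at 57.8 ± 3.9 against 76.2 ± 6.5 FPKM. Of 28 endothelial genes, 18 lay higher, 0 passed, and the mean was 0.087 (camera adjusted p = 0.159). Without wild-type replicate 3 camera called the list higher (mean 0.25, adjusted p = 0.00027), as it did without both female libraries (0.30, 3.6e-05), with array weights (0.32, 0.000168) and in voom with quality weights (0.31, 0.000274). With an estimated correlation the adjusted p of the endothelial list in all 6 libraries was 0.936. Of 14 inflammation and adhesion genes 0 passed, with Nfkbia at 51.3 ± 1.7 against 77.6 ± 14.2 FPKM, Irf1 at 12.5 ± 2.6 against 9.59 ± 1.03 FPKM and a list mean of -0.012 (camera adjusted p = 0.993). Of 31 TGF-beta and BMP genes 0 passed. Tgfbi had a log2 fold change of -0.58 from 151 ± 22 FPKM in wild-type, and the list mean of -0.017 and median of -0.011 differed in sign from the camera test (adjusted p = 0.993). Without wild-type replicate 3 camera called this list lower (adjusted p = 0.0245, mean -0.13), and without both female libraries as well (0.00177, mean -0.16). With an estimated correlation the adjusted p of this list in all 6 libraries was 0.996. Of 7 lymphatic endothelial genes 0 passed, with Sema3d at 15.6 ± 0.3 against 20.9 ± 3.6 FPKM, Pdpn at 5.89 ± 1.79 against 3.57 ± 2.19 FPKM and a mean of 0.081 (camera adjusted p = 0.660).

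Fat and energy metabolism genes lay higher in EC-Jag1KO libraries as lists. Scd1, the fatty acid desaturase gene, stood at 418 ± 390 FPKM in wild-type and 1067 ± 295 FPKM in EC-Jag1KO aorta (n = 3 each), and Slc2a4, the insulin-responsive glucose transporter gene, at 21.8 ± 5.8 against 32.6 ± 3.6 FPKM. Of 19 adipocyte genes, 17 lay higher with a list mean of 0.60 (camera adjusted p = 0.0064, and an adjusted p of 0.873 with an estimated correlation). Of 37 nuclear oxidative phosphorylation genes, 33 lay higher with a mean of 0.19 (camera adjusted p = 0.0048, and an adjusted p of 0.879 with an estimated correlation), including Sdhb at 72.8 ± 21.5 against 96.8 ± 18.0 FPKM and Atp5o, which other genes overlap, at 63.8 ± 12.3 against 79.98 ± 14.1 FPKM. All 12 tested mitochondrially encoded genes lay higher, mt-Nd5 by 0.39 and mt-Nd6, which overlaps it, by 0.37, with a list mean of 0.30 (camera adjusted p = 0.0064, and an adjusted p of 0.873 with an estimated correlation). Single members did not pass in any of these 3 lists. The mean adipocyte level was 4.42 in wild-type replicate 2 and 5.95 to 6.61 in the other 5 libraries, and without that library the list mean was -0.014 for adipocyte, 0.025 for oxidative phosphorylation and 0.081 for mitochondrially encoded genes (adjusted p = 0.977, 0.386 and 0.336). The 3 calls also ended without EC-Jag1KO replicate 1 (0.0732, 0.315 and 0.0518) or without EC-Jag1KO replicate 2 (0.0672, 0.213 and 0.129). The means were 0.42, 0.057 and 0.235 without EC-Jag1KO replicate 1 and 0.63, 0.099 and 0.21 without EC-Jag1KO replicate 2. Without wild-type replicate 3 the means were 1.01, 0.33 and 0.49, and without EC-Jag1KO replicate 3 the oxidative phosphorylation mean was 0.43. The 3 means, in the same order, were 1.16, 0.56 and 0.63 without both female libraries, 0.96, 0.47 and 0.45 with array weights and 0.89, 0.42 and 0.43 in voom with quality weights. With the striated muscle covariate the means were 0.44 for adipocyte, 0.032 for oxidative phosphorylation and 0.15 for mitochondrially encoded genes (adjusted p = 0.258, 0.623 and 0.325), and with the adipocyte covariate they were -0.014 and 0.067 for the last pair (0.618 and 0.292). Without both wild-type replicate 2 and EC-Jag1KO replicate 3 the adipocyte call ended (mean 0.14, 0.313), while oxidative phosphorylation (0.26, 1.08e-10) and mitochondrially encoded genes (0.22, 0.0191) stayed called higher. Those calls rest on the preset correlation of 0.01, where 0.80 and 0.72 were estimated for these lists in all 6 libraries. Of 17 brown fat genes 0 passed, with the channel gene Kcnk3 at 10.6 ± 8.2 against 24.0 ± 6.0 FPKM, Elovl6 at 8.25 ± 5.93 against 19.3 ± 8.1 FPKM and a mean of 0.40 (camera adjusted p = 0.112). Camera called brown fat higher without wild-type replicate 1 (0.0426) or wild-type replicate 3 (2.67e-05), without both female libraries (0.000488), with array weights (0.00504) and in voom with quality weights (0.00354), and without wild-type replicate 2 its mean was -0.21. The adjusted p of brown fat with an estimated correlation was 0.936 in all 6 libraries.

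Macrophage genes lay higher and red cell genes lower in EC-Jag1KO libraries as lists. Gpnmb, a glycoprotein gene of phagocytes, stood at 9.19 ± 1.28 FPKM in wild-type and 13.6 ± 1.7 FPKM in EC-Jag1KO aorta (n = 3 each), and Fcer1g, a signalling chain of Fc receptors, at 10.6 ± 1.3 against 13.8 ± 0.9 FPKM. Of 20 macrophage genes, 16 lay higher with a mean of 0.20 (camera adjusted p = 0.0048), which became 0.853 with an estimated correlation. Hbb-bs, a beta-globin gene, stood at 545 ± 190 against 229 ± 155 FPKM and Hbb-bt at 47.1 ± 12.9 against 20.2 ± 16.7 FPKM. These near-identical copies may share reads. All 7 erythroid genes lay lower with a mean of -1.01 (adjusted p = 0.0048), and the adjusted p was also 0.853 with an estimated correlation. The macrophage call ended without wild-type replicate 2 (0.0729, mean 0.15), wild-type replicate 3 (0.0811, mean 0.15) or EC-Jag1KO replicate 2 (0.0672, mean 0.18). The erythroid call ended without EC-Jag1KO replicate 1 (0.0518, mean -0.53) or EC-Jag1KO replicate 2 (0.0517, mean -0.999). With the striated muscle covariate both calls ended (0.0633 and 0.0766) while the means were 0.19 for macrophage and -0.96 for erythroid genes. The macrophage call also ended with array weights (mean 0.061, 0.624), voom with quality weights (0.10, 0.341), both female libraries left out (0.13, 0.255) and wild-type replicate 2 and EC-Jag1KO replicate 3 left out (0.13, 0.185), where the erythroid mean was -1.76. That mean was -1.97 with array weights and -1.87 in voom with quality weights. The lymphocyte list had 2 members past the filter and was tested as a list only without it, where camera called its 24 genes lower (mean -0.044, adjusted p = 0.0308, and an adjusted p of 0.841 with an estimated correlation). Igkc, an antibody light chain gene, stood at 64.9 FPKM in EC-Jag1KO replicate 3 and 1.48 to 13.5 FPKM in the other libraries, and Ighm at 39.3 FPKM against 3.69 to 7.79 FPKM. Of 6 neutrophil and monocyte genes 0 passed, with Lcn2 at 0.418 ± 0.626 against 2.09 ± 2.10 FPKM, Plac8 at 1.95 ± 0.90 against 2.73 ± 0.56 FPKM and a mean of 0.62 (camera adjusted p = 0.141; 0.873 with an estimated correlation, 0.0188 without EC-Jag1KO replicate 1 and a mean of -0.25 without EC-Jag1KO replicate 3), while S100a8 stood at 28.8 FPKM in EC-Jag1KO replicate 3 and at 3.99 FPKM or less elsewhere.

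**Figure D3:**
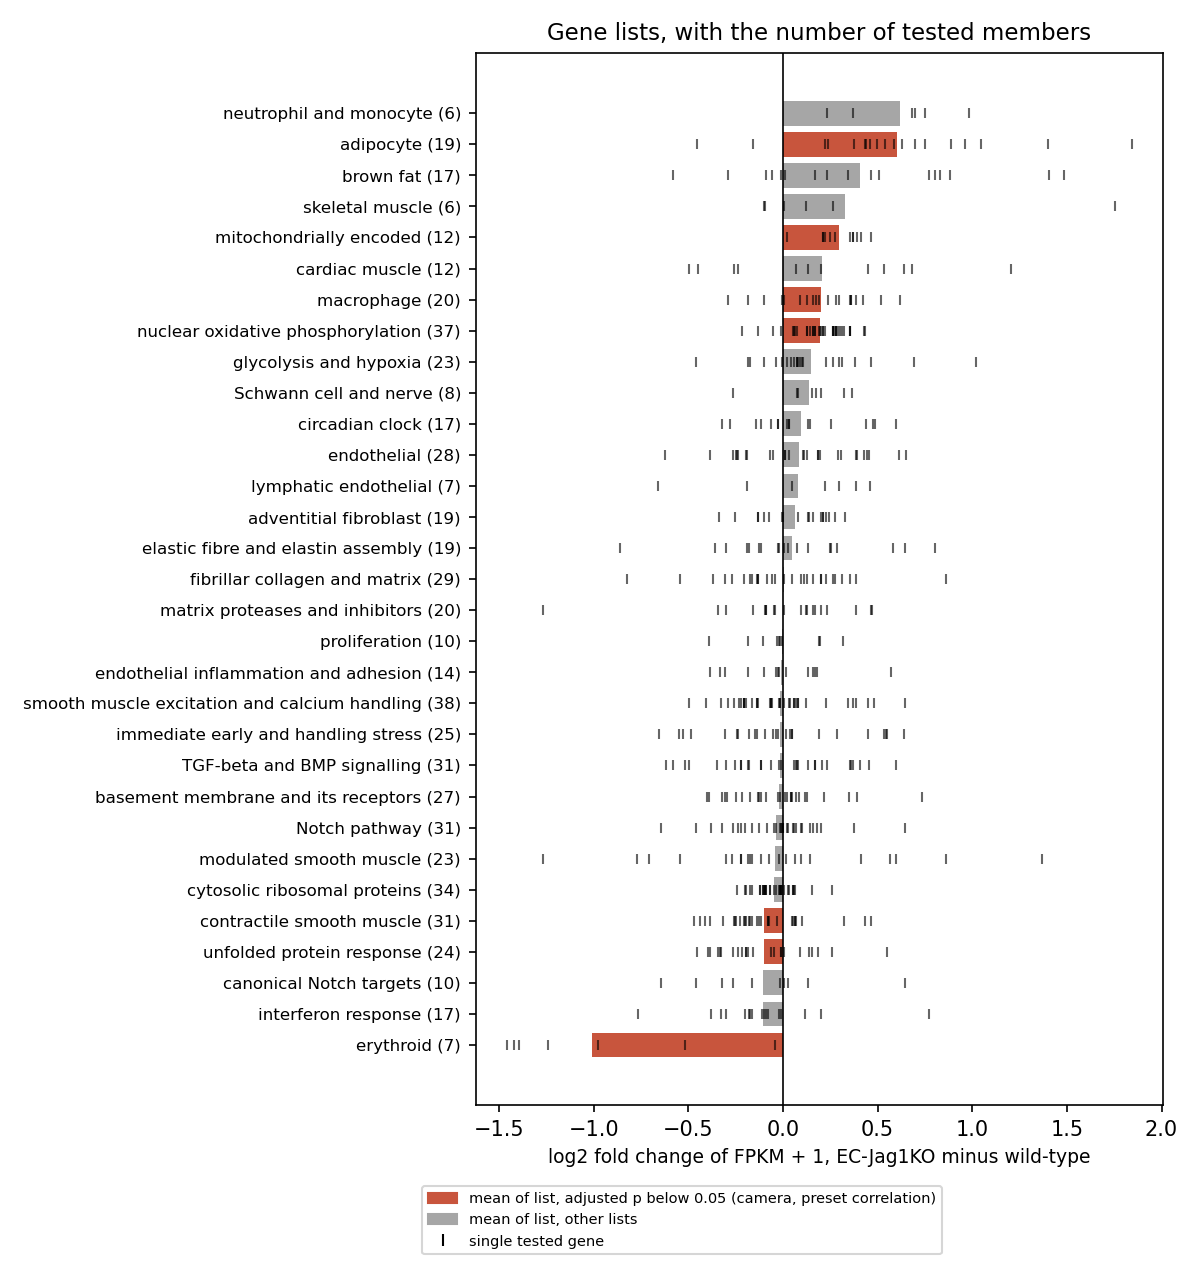
Mean log2 fold change of FPKM + 1 in EC-Jag1KO against wild-type aorta (bars, horizontal axis) for the 31 tested gene lists, with a tick for each tested gene and the number of tested genes after the name. The 7 red bars passed camera with the preset correlation, from -1.01 for erythroid to 0.60 for adipocyte genes, and 0 lists passed with an estimated correlation.

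Of the remaining lists, none was called in the primary camera test. Glycolysis and hypoxia genes had a mean of 0.15 (camera adjusted p = 0.0575) over 23 members. Adm rose over the list alone (adjusted p = 0.0099 in limma), and Egln3, a hypoxia-induced oxygen sensor gene, stood at 2.74 ± 0.84 against 4.94 ± 0.31 FPKM. Without EC-Jag1KO replicate 2 Adm did not pass over the list (0.0541), and camera called the glycolysis list without EC-Jag1KO replicate 3 (0.0301) or wild-type replicate 3 (0.0041). It also called this list under median-ratio scaling (0.0469), quantile normalization (0.0152), scaling without the 100 most abundant genes (0.0405), a mean of at least 5 FPKM (0.0328), array weights (0.00126), removal of the length trend (0.0226), voom (0.0449), voom with quality weights (0.000857) and both female libraries left out (0.00361). Its means there were 0.14 to 0.28, and the adjusted p was 0.873 with an estimated correlation. Of 6 skeletal muscle genes, Myh7, a slow myosin gene, rose over the list alone from 0.307 ± 0.342 to 3.54 ± 1.72 FPKM (adjusted p = 0.0046, and 0.0223 or less with each library left out), Tnnt3, which overlaps Prr33, stood at 2.33 ± 0.64 against 2.96 ± 0.30 FPKM, and the list mean was 0.33 (camera adjusted p = 0.302). Members of the other lists did not pass over the list alone. Ryr2 stood at 6.43 ± 1.46 against 4.25 ± 1.05 FPKM and Hspb7 at 198 ± 60 against 144 ± 42 FPKM among 12 cardiac muscle genes (mean 0.21, adjusted p = 0.841). Pdgfra stood at 15.3 ± 0.5 against 19.5 ± 2.0 FPKM and Serpinf1 at 183 ± 11 against 145 ± 14 FPKM among 19 adventitial fibroblast genes (mean 0.062, 0.302). Scn7a stood at 4.39 ± 0.15 against 5.75 ± 0.39 FPKM and Prx at 5.08 ± 0.22 against 4.07 ± 0.43 FPKM among 8 Schwann cell and nerve genes (mean 0.14, 0.112). Mesothelial genes, of which 3 passed the filter, were tested as a list only without it, where camera called 12 of them higher as a list (mean 0.22, adjusted p = 0.0067, and an adjusted p of 0.579 with an estimated correlation). Cldn15 stood at 2.80 ± 0.90 against 5.15 ± 1.60 FPKM and Gpm6a at 2.48 ± 1.21 against 1.73 ± 0.33 FPKM.

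Stress and regulatory lists also held isolated members. Atf3, an immediate early transcription factor gene, stood at 26.7 ± 2.1 FPKM in wild-type and 39.9 ± 6.9 FPKM in EC-Jag1KO aorta, and Myc at 1.59 ± 0.24 against 3.06 ± 0.67 FPKM, among 25 immediate early and handling stress genes whose mean of -0.014 and median of -0.038 differed in sign from the camera test (adjusted p = 0.993). Clock stood at 5.03 ± 0.33 against 7.21 ± 0.94 FPKM and Nfil3 at 6.29 ± 1.62 against 10.1 ± 2.9 FPKM among 17 circadian genes (mean 0.096, 0.343). Prc1 stood at 1.48 ± 0.38 against 0.887 ± 0.213 FPKM and Pcna at 31.6 ± 2.1 against 27.6 ± 1.1 FPKM among 10 proliferation genes (mean -0.0048, 0.891). Bst2 stood at 40.3 ± 10.8 against 69.2 ± 15.9 FPKM and Gbp2 at 14.2 ± 4.6 against 10.4 ± 0.7 FPKM among 17 interferon response genes (mean -0.11, 0.302). Camera called this list lower without wild-type replicate 2 (mean -0.24, 0.0074), with the adipocyte covariate (-0.24, 0.0194) and without both wild-type replicate 2 and EC-Jag1KO replicate 3 (-0.23, 0.00841), and the adjusted p was 0.936 with an estimated correlation in all 6 libraries. Rpl3 stood at 232 ± 10 against 279 ± 40 FPKM and Rpl15 at 129 ± 4 against 113 ± 18 FPKM among 34 cytosolic ribosomal protein genes (mean -0.047, 0.478), which camera called lower without EC-Jag1KO replicate 2 (mean -0.17, adjusted p = 0.0352) and higher without EC-Jag1KO replicate 3 (mean 0.16, 4.66e-05). Camera also called ribosomal protein genes higher with array weights (0.0155), without both female libraries (0.000312) and without both wild-type replicate 2 and EC-Jag1KO replicate 3 (8.54e-07). It called them lower with the striated muscle covariate (0.0181). With an estimated correlation in all 6 libraries the adjusted p was 0.976 for ribosomal protein genes.

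The libraries did not separate cleanly by genotype. EC-Jag1KO replicate 3 lay at 33.8 on the first principal component, which held 32.0% of the variance, against 0.037 or less for the other 5 libraries. Wild-type replicate 2 lay at -28.4 on the second component (28.9%). The correlation of log2(FPKM + 1) between libraries of the same genotype exceeded that between genotypes by 0.0028 on average. Each library's deviations from the median of the other 5 were set against gene length. The Spearman correlation across genes was 0.443 in EC-Jag1KO replicate 3. It was -0.285 to 0.1001 in the other libraries, and genes are not independent replicates in such a correlation. Ribosomal protein genes took 1.88% of reads in EC-Jag1KO replicate 3 and 2.28% to 2.82% elsewhere. The sex check, with Xist at 26.9 and 40.7 FPKM in replicate 3 of each genotype and at 0.0738 FPKM or less in the other 4 libraries, and Ddx3y at 15.2 to 20.3 FPKM in those 4, put 1 female and 2 male libraries in each group.

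**Figure D4:**
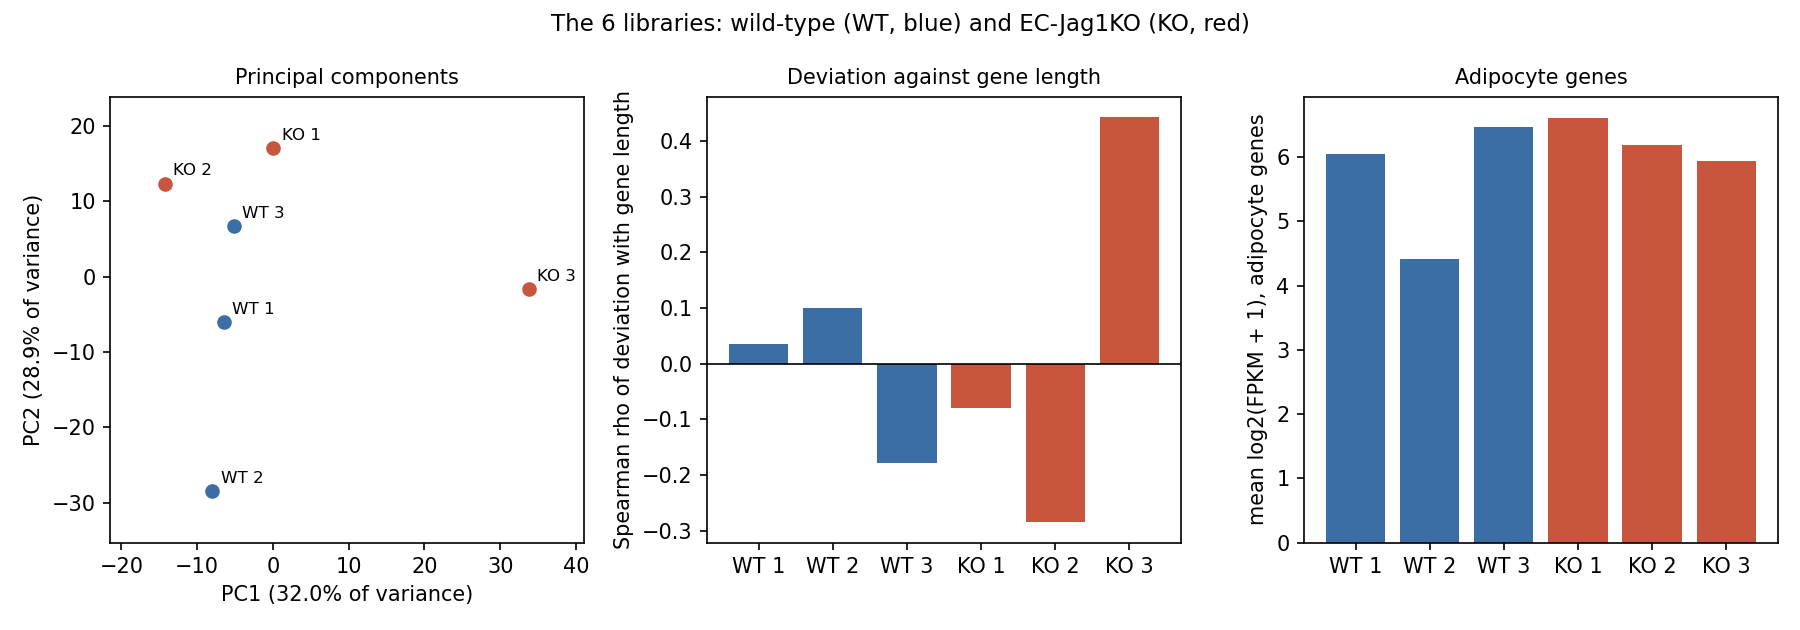
The 6 libraries, wild-type in blue and EC-Jag1KO in red: scores on the first and second principal components of log2(FPKM + 1) (left), Spearman correlation of each library's deviations with gene length (middle) and mean log2(FPKM + 1) of adipocyte genes (right). EC-Jag1KO replicate 3 stands apart with a correlation of 0.443 and wild-type replicate 2 with an adipocyte level of 4.42.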

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

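Sex as a covariate, length correction, both voom fits and the 2 further sets of left-out libraries were chosen after the data were seen, the rest before; causes were not tested except where a filter changes the genes tested. List values here are mean log2 fold changes. Genes past the adjusted threshold numbered 1647 with array weights, 43 in voom with quality weights and 1 with the sex covariate (RP24-479J14.1). They numbered 2 with both female libraries left out (Gm6472 and Gm10020), 0 to 4 with each library left out and 0 in the remaining settings. In the left-out wild-type and EC-Jag1KO replicates 3 these 2 genes went the other way, Gm6472 at 43.6 and 1.01 FPKM and Gm10020 at 12.8 and 6.15 FPKM. Genes at an unadjusted p under 0.05 numbered 1436 with no filter, 612 at a mean of 5 FPKM or more, 4215 with array weights, 2218 with voom and quality weights, 58 at an absolute log2 fold change of 1 or more, 1592 with the striated muscle covariate and 594 to 1437 with a library left out. Lists called numbered 9 with no filter, adding lymphocyte and mesothelial genes, 0 with an estimated correlation, 0 with fry's test of change in a single direction, 1 at an absolute mean of 1 or more, 3 with the adipocyte and 3 with the striated muscle covariate, 15 without both female libraries and 2 to 10 with a library left out. The replicate block gave 0 genes and 9 lists, adding brown fat and glycolysis; the deviations of same-numbered libraries correlated at 0.055, 0.051 and -0.050, none over 0.1, so the numbers were not taken as pairs. Across genotypes wild-type replicates 1 and 2 correlated best with their own number (0.982 and 0.970), wild-type replicate 3 with EC-Jag1KO replicate 1 (0.979), and EC-Jag1KO replicates 2 and 3 with wild-type replicate 1 (0.981 and 0.970). The 20 leading genes kept their sign in every setting that tested them (15 of them at a mean of 5 FPKM or more). They were picked for groups that do not overlap, so leaving out a library could not turn a sign, and stability cannot be read from this. Signs turned as follows. Matrix proteases: pseudocount 0.1 0.0027, no filter 0.016, mean of 5 FPKM 0.0155, median-ratio scaling 0.0017, quantile 0.0034, scaling without the top 100 genes 0.0050, adipocyte covariate 0.0159, striated covariate 0.0026, voom 0.0049, wild-type 2 and EC-Jag1KO 3 out 0.0066. No filter: modulated smooth muscle 0.0049, endothelial inflammation 0.038, proliferation 0.011. Mean of 5 FPKM: modulated smooth muscle 0.0041, endothelial inflammation 0.0074. Array weights: Notch pathway 0.00053, endothelial inflammation 0.035, elastic fibre -0.054, collagen -0.12, cardiac -0.014, neutrophil -0.45, lymphatic -0.0064, immediate early 0.13, ribosomal 0.13, Ighm -0.63, Lcn2 -0.084. Adipocyte covariate: endothelial -0.042, TGF-beta 0.066, brown fat -0.19, lymphatic -0.105, proliferation 0.0051, oxidative phosphorylation -0.014. Striated covariate: excitation 0.034, TGF-beta 0.0035, lymphatic -0.011, immediate early 0.034. Length removed: collagen -0.027. Voom with quality weights: Notch pathway 0.0062, endothelial inflammation 0.028, elastic fibre -0.026, collagen -0.0999, neutrophil -0.71, immediate early 0.082, ribosomal 0.11, Ighm -0.46. Both female libraries out: endothelial inflammation 0.041, elastic fibre -0.017, collagen -0.14, neutrophil -0.31, interferon 0.057, ribosomal 0.18, Ighm -0.57. Wild-type 2 and EC-Jag1KO 3 out: TGF-beta 0.017, brown fat -0.15, neutrophil -0.46, lymphatic -0.11, immediate early 0.0061, ribosomal 0.19, Jag1 -0.18, Igkc -0.92, Ighm -0.79. With each library left out, values ranged from -0.091 to 0.40 for Jag1, -0.061 to 0.0059 for the Notch pathway, -0.082 to 4.2e-05 for modulated smooth muscle, -0.066 to 0.039 for excitation, -0.012 to 0.25 for endothelial, -0.063 to 0.047 for endothelial inflammation, -0.012 to 0.085 for elastic fibre, -0.071 to 0.073 for collagen, -0.023 to 0.012 for proteases, -0.13 to 0.046 for TGF-beta, -0.014 to 1.01 for adipocyte, -0.21 to 0.87 for brown fat, -0.18 to 0.46 for cardiac, -0.25 to 1.10 for neutrophil, -0.15 to 0.24 for lymphatic, -0.088 to 0.052 for immediate early, -0.040 to 0.042 for proliferation, -0.24 to 0.048 for interferon, -0.17 to 0.16 for ribosomal genes, -0.18 to 1.82 for Igkc and -0.61 to 0.95 for Ighm. The remaining list comparisons kept direction: 632 also kept their side of the threshold, 34 gained a call and 51 lost it, among the gains ribosomal genes with the striated covariate (-0.18, adjusted p = 0.0181), and no list has a value where its own genes are the covariate. Depth limits genes near 0.0492 FPKM, the value of 3 reads at the median length in the smallest library.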

Other observations

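The tests of the Hox genes, of gene length, blood cells, sex and the Jag1 region, of the 2 libraries left out together and of other splits, and the use of the adipocyte level against fat, were chosen after the result was seen, while the covariates, the estimated correlation and each single left-out library were planned. Hox genes, which mark position along the body axis, lay mostly lower in EC-Jag1KO aorta: 17 of 19 tested were below 0, with a mean log2 fold change of -0.23, and 17 were below 0 under each scaling tried. Hoxb6 stood at 19.7 ± 2.9 against 12.6 ± 1.8 FPKM, Hoxb7 at 10.97 ± 1.03 against 7.74 ± 0.38 FPKM and Hoxb8 at 7.59 ± 1.28 against 5.04 ± 0.53 FPKM (SD, n = 3 each). These 3 passed limma's test adjusted over the Hox genes alone (adjusted p = 0.0382, 0.0382 and 0.0484), a list picked from these values; 2 passed without wild-type replicate 1 and 0 when any other single library was left out.

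Further genes, picked after their values were seen, did not pass the adjusted threshold. Ghr, the growth hormone receptor gene, stood at 23.4 ± 6.5 FPKM in wild-type and 51.3 ± 12.7 FPKM in EC-Jag1KO aorta, and Igfbp5 at 162 ± 13 against 92.6 ± 23.4 FPKM. Ramp3, which encodes a partner of the adrenomedullin receptor, stood at 2.30 ± 0.21 against 0.371 ± 0.410 FPKM. Mgl2, a macrophage lectin gene, stood at 7.61 ± 1.37 against 14.2 ± 1.2 FPKM and Clec10a, a closely related gene from which its reads are not separated with certainty, at 1.93 ± 0.42 against 4.24 ± 0.53 FPKM.

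The 20 leading genes were set against 3 technical explanations, and an effect of genotype stays open beside them. With the adipocyte level as a covariate the median gene kept 98.57% of its fold change (84.0% to 112%), and with the length trend removed it kept 99.59% (97.1% to 111%). Both measures overlap between the groups and the genes were picked by small p, so these values leave fat amount and gene length open. Of the 20 genes, 0 lie within 20 megabases of Jag1, which argues against DNA carried along there as the local source of these 20 differences. Few tested genes lie in that window, so a count of 0 does not show that no such DNA was carried along. Slc52a3, which lies there, was kept out of the 20 by the condition of a mean of at least 5 FPKM. Genes near Jag1 as a class stay open: 7 of 282 (2.48%) had a p under the 0.01 limit against 244 of 11883 elsewhere (2.05%, one-sided Fisher's exact p = 0.364), among them Procr at 16.8 ± 5.7 against 36.3 ± 2.6 FPKM and Slc52a3 at 1.75 ± 0.05 against 0.416 ± 0.192 FPKM.

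Adipocyte and oxidative phosphorylation genes were called higher in EC-Jag1KO libraries, with means of 0.60 and 0.19; these calls were lost with an estimated correlation (adjusted p = 0.873 and 0.879) and the means were -0.014 and 0.025 without wild-type replicate 2. With the length trend removed the oxidative phosphorylation mean was 0.1938, which argues against gene length. Unequal amounts of fat on the dissected aortas stay open: the oxidative phosphorylation mean was -0.0138 with the adipocyte covariate, but also 0.032 with the striated muscle covariate. Without both wild-type replicate 2 and EC-Jag1KO replicate 3 the adipocyte mean was 0.14 (camera adjusted p = 0.313) while the oxidative phosphorylation mean was 0.26 (1.08e-10). Camera there assumed a correlation of 0.01, where 0.80 was estimated for the oxidative phosphorylation list in all 6 libraries. The values of those 4 libraries, chosen after the data were seen, therefore cannot decide whether fat was its whole source. Whether genotype changed the amount of fat was not tested.

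EC-Jag1KO replicate 3 stood apart from the other 5 libraries. Gene length accounted for 15.54% of its squared deviation (0.153% to 8.33% in the others), a share that also counts the noise of single genes. With the length trend removed, its score on the first principal component fell from 33.8 to 22.5. The highest score of another library rose from 0.037 to 11.7. Its mean correlation with the other libraries rose from 0.9656 to 0.9697, where wild-type replicate 2 then had 0.9718. Part of its separation thus followed gene length and part remained, so a loss of short transcripts stays open as a partial cause. Of the 500 genes that deviated most from the mean of the other EC-Jag1KO libraries, 77.2% lay lower, which argues against added blood and lymphoid cells as the whole cause. Its deviations from its group mean correlated at -0.0496 with those of the other female library, which argues against sex as the whole cause. Such deviations also carry what sets the rest of a group apart. Those of EC-Jag1KO replicates 2 and 3 correlated at -0.763, and those of wild-type replicates 2 and 3 at -0.736. A part played by sex therefore stays open. No other biological explanation was tested.

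The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Genes past the adjusted threshold numbered 0 in the real split and at most 1 in another, and with 0 in the real split the number of splits with as many is fixed. Genes at an unadjusted p under 0.05 numbered 938 and at most 1073 (2 of 10 as many), and lists called numbered 7 and at most 14 (10 of 10 as many).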
